A study of Mus musculus with 2 samples.

How the data were processed

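Gene expression was measured in uterine stromal cells of C57BL/6 mice on day 4 of pregnancy with Affymetrix 3' expression arrays. The samples were 1 array of cells from floxed control mice and 1 array of cells from mice in which Msx1 and Msx2 were ablated in the uterus with the PRcre line. Per the labels' protocols, uterine pieces were digested with dispase and pancreatin, the epithelial clumps were discarded, and the remaining tissue was digested with collagenase to release the stromal cells. The series design text and the treatment protocol give 5 mice per genotype, whereas the extraction protocol gives 4 per genotype, and the RNA of each genotype was pooled before hybridization.

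The deposited values are linear signal intensities, 1 per probe set and array, made by the authors with MAS5 in Affymetrix Expression Console 1, per the submitters' processing notes. MAS5 combines the probe pairs of a probe set into a single signal after subtracting mismatch and background signal. In the deposited intensity table the mean signal, after removal of the highest and lowest 2% of probe sets, was 150 in each array, which shows that the arrays had been scaled to a common level. The background and scaling settings and detection calls were not given in the sources used here. MAS5 signals of dim probe sets are noisy on a log scale, and subtraction of mismatch signal makes ratios between small signals unstable.

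The table held 45101 probe sets, of which 64 were Affymetrix control probe sets and were used only for quality values. The platform annotation gave 1 gene symbol for 34945 probe sets, several symbols for 932 and none for 9160. Only probe sets with 1 symbol were used for genes. The Entrez IDs of 34741 of them were found in the GRCm38.p6 RefSeq gene table, and 0 symbols needed an update. No genome build was given for the probe design in the sources used here, so no coordinates are printed.

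Signals were turned into log2 values without further scaling, and all ratios are null minus control. A gene was represented by its probe set with the highest mean log2 signal over both arrays. In place of detection calls a floor was set at the 50th percentile of all non-control probe sets of an array, which was a signal of 31.0 in the control array and 30.1 in the null array. A signal under the floor is not evidence that a gene was silent. A gene was used when at least 1 of its signals was above the floor, and a signal under the floor was raised to it, so that the fold is then in general a lower bound and is printed as "at least". Because the floors of the arrays differ slightly, the floored ratio was no lower bound for 35 of 696 such genes, with the opposite sign in 32, and none of these ratios was larger than 0.045. The smooth muscle gene Casq2 was the 1 list member among them, and with its measured ratio the median of that list was unchanged at 0.37. Of 18193 genes, 11833 were used and 6360 were under the floor in both arrays.

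Each genotype had 1 array, so the spread between animals or between hybridizations could not be estimated and no p-value was computed. Genes were called by size alone, at 2-fold. As a scale of the noise of single probe sets, the log2 ratios of the 2 brightest probe sets of the same gene were compared, both above the floor in both arrays. Over 4690 genes the SD of a single probe set's log2 ratio, from these differences, was 0.27, and it was 0.32, 0.28 and 0.20 in the dimmest, middle and brightest tertile of signal. This SD covers noise of single probe sets and transcript isoforms. Errors shared by both probe sets of a gene cancel in it. It does not cover differences between mice, pools or hybridizations.

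For 32 gene lists the median log2 ratio of the members above the floor was set against the medians of 10000 random lists of the same size, drawn from the 10 deciles of mean signal in the same numbers. The percentile describes these 2 arrays and is not a significance level, since co-regulated genes are not independent. A median was computed for the 29 lists with at least 4 members above the floor. The lists named 581 different genes on the array, of which 27 were in more than 1 list. The lists for B cells, erythroid cells and the blastocyst had too few members above the floor. The lists, the floor, the size threshold, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Msx1, Msx2 and Pgr; the 10 highest and 10 lowest ratios among genes above the floor in both arrays; the 4 highest bounds in each direction; and up to 4 members of each list with the largest ratios. It skipped clone identifiers and genes whose other probe sets above the floor had the opposite sign, except among list members. The list members Axin2, Nusap1, Pcna, Prom1, Krt8, Krt18, Krt19, Epcam, Fgf9, Fgf10, Fgf18, Eomes, Csf3, Casq2 and Loxl3 are also named in the report and were chosen after their values were seen. So were Cd3g, Cd3e, Cd4, Cd8a, Gli1, Ptch1, Cdc20 and Tyms.

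The alternatives were centring on the median ratio, quantile normalization, a loess curve of ratio on mean signal with a span of 0.3, no floor, a floor at the 65th percentile, an offset of each array's 25th percentile added before log2, the median over a gene's probe sets, leaving out probe sets that can match several transcripts (_x_at and _s_at), and thresholds of 1.5-fold and 3-fold. List medians over only the members above the floor in both arrays were added after the data were seen. The procedure was tested on simulated data with the real signals, the probe set SD as noise and 200 genes with known log2 ratios. Of genes simulated with a log2 ratio of 1.5, 92.0% were called, and of those with -1.5, 98.0%. Of those simulated with 2.5, 100% were called, and of those with -2.5, 94.0%. Among 11426 simulated unchanged genes 2 passed the threshold. The changed genes were drawn only from genes well above the floor, and the noise was the same at every signal. Differences between mice, pools or hybridizations were not simulated. These rates are therefore not the error rates of the calls on the real arrays, least of all for dim genes. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.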

Results

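Uterine stromal cells, the connective tissue cells that surround the uterine epithelium and later form the decidua, were profiled on day 4 of pregnancy, close to the time when the mouse blastocyst attaches. The comparison asked which stromal transcripts differ when the homeobox transcription factors Msx1 and Msx2 are absent, with signals sent from stroma to epithelium through the Fgf and Wnt families named in the sample labels. There was 1 array of pooled RNA for floxed control mice and 1 for Msx1/Msx2-null mice. Every value below is therefore a single measurement of a pool without replicate error, and a difference between the arrays may reflect the genotype, the pooled mice or the hybridization. The median signal of all probe sets was 31.2 in the control array and 30.2 in the null array. The 100 brightest probe sets held 10.9% of the summed signal in each array. The 18 hybridization spike-in probe sets had log2 ratios between -0.12 and 0.22. The 3'/5' signal ratio, which goes up as RNA is degraded, was 0.967 in the control and 1.28 in the null array for Gapdh, and 1.80 and 2.33 for Actb.

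Both targeted genes were lower in the null array on their probe sets above the floor. Msx1 had a signal of 1581 in the control array and 23.0 in the null array on probe set 1448601_s_at, at least 52.6-fold lower. Its second probe set, 1417127_at, went from 414 to 2.64, at least 13.8-fold lower. Msx2 was dim already in control cells. Its signal was 63.7 in the control and 14.5 in the null array on probe set 1449559_at, at least 2.12-fold lower, and its other probe set, 1438351_at, was under the floor in both arrays at 15.9 and 2.85. Whether these probe sets lie inside the deleted segments was not given in the sources used here. PRcre is a knock-in that places Cre recombinase under the control of the progesterone receptor gene. Pgr itself was not lower in the null array, with signals of 1891 and 2663 on its brightest probe set, 1.41-fold higher, and the other 2 probe sets were 1.18-fold and 1.43-fold higher.

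Outside the targeted genes most transcripts were close in both arrays. Of 11833 genes above the floor, 188 were at least 2-fold higher and 213 at least 2-fold lower in the null array, together 3.39%. Of these, 144 higher and 174 lower genes were above the floor in both arrays, and the remaining 44 and 39 were bounds. The log2 signals correlated across genes with a Pearson r of 0.954, and 90 of the called genes had a second probe set above the floor in both arrays. The second probe set had the same sign in 83 of them (92.2%), against 63.9% over all genes with such a pair, and in 64 it also passed 1.5-fold. Large ratios agree in sign more often than small ones whatever their cause. Both probe sets read the same pools, so this bears on probe noise and not on the genotype. Both counts depended on the floor, being 1797 higher and 1772 lower with no floor and 97 and 123 with a floor at the 65th percentile.

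**Figure D1:**
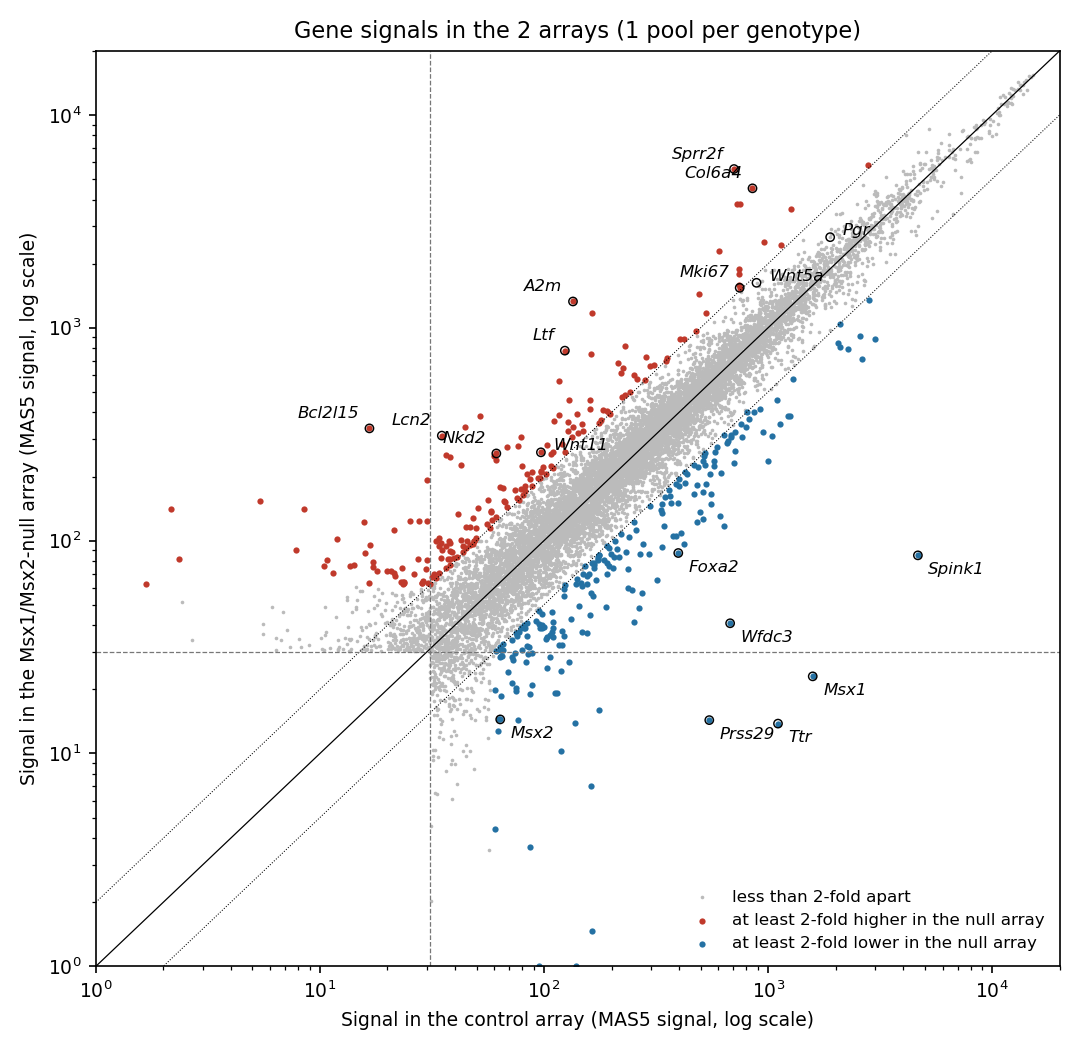
MAS5 signal of each gene above the floor in at least 1 array, control array on the x axis and Msx1/Msx2-null array on the y axis, both on log scales, with 1 point per gene, coloured after signals under the floor were raised to it, and signals under 1 drawn at 1. The solid line marks equal signals, dotted lines mark 2-fold, dashed lines mark the floors, and Msx1, Ttr, Prss29, Spink1 and Wfdc3 lie farthest below the diagonal among labelled genes.

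Among genes measured in both arrays the lowest ratio was that of Spink1, a secreted serine protease inhibitor of the uterine glands, which went from 4657 to 85.2 and was 54.6-fold lower. Ttr, the carrier of thyroid hormone and retinol-binding protein, was at least 36.8-fold lower, from 1106 to 13.8, and the implantation serine protease gene Prss29 was at least 18.2-fold lower, from 546 to 14.3. Wfdc3 was 16.5-fold lower, and Foxa2, the transcription factor of the gland epithelium, was 4.54-fold lower, from 397 to 87.4. Cldn8, a tight junction claudin, was 6.06-fold lower, the keratin gene Krt23 5.39-fold lower and Pof1b 4.35-fold lower. The remaining genes named by the rule were Csf2rb2, a cytokine receptor beta subunit (5.46-fold lower), Kbtbd8 (4.87-fold), Slain1 (4.82-fold), the synaptic vesicle protein gene Sv2b (4.67-fold) and the tachykinin gene Tac2 (at least 5.88-fold).

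The highest ratio among genes measured in both arrays was that of A2m, the protease inhibitor alpha-2-macroglobulin, which went from 135 to 1328 and was 9.87-fold higher. Lcn2, an iron-siderophore-binding lipocalin, was 8.90-fold higher, Sprr2f, a small proline-rich protein of the epithelium, was 7.90-fold higher with signals of 704 and 5565, and the lactoferrin gene Ltf was 6.30-fold higher. Gcnt3, a mucin-type glycosyltransferase, was 7.69-fold higher and Spink8 6.89-fold higher. Ramp3, an accessory protein of the adrenomedullin receptor, went from 163 to 1168, 7.15-fold higher. Fam107a was 7.41-fold higher, the granzyme gene Gzmf 6.44-fold higher, and Col6a4, a collagen VI chain, 5.30-fold higher with signals of 851 and 4516. Among genes under the floor in control cells, Bcl2l15 was at least 10.8-fold higher, the retinoic acid-binding protein gene Crabp1 at least 6.20-fold, the beta-defensin gene Defb3 at least 4.55-fold and Ms4a8a at least 4.53-fold. Sprr2f, Gzmf, Csf2rb2, Defb3 and Prss29 belong to families of closely similar genes, so signal from a relative cannot be separated on these probe sets.

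Wnt ligands were on balance higher in the null array, while few Fgf ligands could be measured. Of 19 Wnt ligand genes, 8 were above the floor, 5 of them higher and 3 lower. Wnt11 went from 96.8 to 260 and was the single ligand past 2-fold, at 2.68-fold higher. Wnt5a, the brightest ligand, went from 887 to 1625, a log2 ratio of 0.87, and its other 2 probe sets above the floor in both arrays gave 1.14 and 0.86. Wnt16 had a log2 ratio of 0.45, and Wnt4, a ligand of the decidual reaction, had -0.54. The median of the ligands was 0.38, at percentile 98.7 of matched random lists, and at percentile 89.5 with no floor. Among 10 measured target genes of beta-catenin, the feedback gene Nkd2 was 4.19-fold higher, from 61.2 to 257. Lef1 and Axin2 had log2 ratios of 0.94 and 0.58, whereas the feedback ubiquitin ligase genes Znrf3 and Rnf43 had -0.99 and -0.83, the latter a bound. The median of the targets was 0.45, at percentile 99.9. Among 20 receptors and secreted antagonists, 2 passed 2-fold, the antagonist genes Dkk2 (2.86-fold lower) and Dkk3 (2.31-fold lower). The antagonist gene Sfrp1 was 1.99-fold lower and Sfrp4 had a log2 ratio of -0.80, and the list's median of -0.05 lay at percentile 19.9.

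Of 22 genes in the Fgf ligand list, 18 were under the floor in both arrays, among them Fgf9, Fgf10 and Fgf18, and 0 of the other 4 passed 2-fold. Fgf1 went from 51.9 to 81.6, a log2 ratio of 0.65. Fgf13, an intracellular Fgf homologous factor and not a secreted ligand, had -0.61. Fgf7 had -0.08, and Fgf4 had -0.12 with its null signal under the floor. The list's median of -0.10 lay at percentile 34.5, where the central 95% of random medians for 4 genes ran from -0.53 to 0.52. Without Fgf13 the list would fall under the minimum of 4 members, so this median does not describe secreted ligands alone. Of 13 Fgf receptor and feedback genes, Spry4, an inhibitor of receptor tyrosine kinase signalling, was at least 2.40-fold lower and the others were within 2-fold, with Spred1 at -0.46, another of its probe sets having the opposite sign, and Dusp5 at 0.33. The sample labels name the Fgf and Wnt families, so these 2 lists may have been chosen by the study on these samples and are not independent evidence of a direction.

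Cell cycle genes were higher as a group. All 31 measured members had a positive log2 ratio, 7 passed 2-fold and 0 were lower. Cdc20 had another probe set of opposite sign. Tyms was above the floor in the null array only, so the sign of its ratio followed from the filter. The proliferation marker Mki67 went from 746 to 1540, 2.06-fold higher. The mitotic motor genes Cenpe and Kif20a were 2.20-fold and 2.10-fold higher, and Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, was 2.09-fold higher. The smallest log2 ratios were 0.17 for Nusap1 and 0.22 for Pcna. The median was 0.78, above all 10000 random medians.

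The medians of the hormone response and decidualization lists lay within the central 95% of random lists, while single members differed by several fold. Among 14 progesterone receptor and response genes 1 passed 2-fold, Acod1, the itaconate-producing enzyme induced by progesterone in uterine epithelium, at 3.55-fold higher. Hoxa11 and Il13ra2 had log2 ratios of 0.80 and 0.66 and Fkbp5 had -0.65, and the median of 0.16 lay at percentile 95.7, or 98.5 with the median over probe sets. Among 10 estrogen receptor and response genes Lcn2 and Ltf were past 2-fold higher, Greb1 was just under it at 1.00, and Lif, the gland cytokine required for implantation, was 2.39-fold lower, from 332 to 139. The median was 0.03, at percentile 53.5, and the mean 0.51. Among 17 decidualization genes, 2 were past 2-fold, the tryptophan dioxygenase gene Tdo2 (3.96-fold lower) and Igfbp3 (3.18-fold lower, from 1128 to 354). Gja1, the gap junction connexin 43, had 0.78, and the median of -0.02 lay at percentile 32.0.

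Other signalling lists were mostly within the range of random lists. Of 28 BMP, activin and TGF-beta genes, the inhibin subunit gene Inhbb was 3.30-fold higher and the BMP-binding gene Bmper 2.99-fold lower, with a median of -0.02. Of 13 hedgehog pathway genes, 7 had positive and 6 negative ratios. Hhip was 2.92-fold lower, with a null signal of 37.2 near the floor, while the brighter Gli1 and Ptch1 had 0.48 and -0.05. The list's median was 0.12, fell to 0.0052 with the median over probe sets and turned to -0.051 without _x_at and _s_at probe sets. Of 14 retinoid genes, Crabp1 alone passed 2-fold, Cyp26b1 had a bound of -0.77 and Aldh1a2 had 0.75, with a median of 0.14 that turned to -0.015 with no floor. Of 14 prostaglandin genes, Hpgds was at least 2.76-fold lower, and the median was -0.08, or -0.24 at percentile 2.23 with no floor. Of 16 Hox genes, Hoxd3 was 2.39-fold higher while Hoxb3, Hoxb9 and Hoxb6 had -0.92, -0.90 and -0.89. Their median of 0.03 depended on the processing, being 0.31 at percentile 99.8 with the higher floor and -0.15 at percentile 5.09 without _x_at and _s_at probe sets. Of 41 extracellular matrix genes, Fmod was 2.10-fold lower and Col6a1 had 0.96, with a median of 0.03. In this list a lookup of gene synonyms had put Loxl3 in the place of Loxl2, and the median was the ratio of Loxl3. Lists outside the central 95% of random lists were the EGF family ligands, with a median of -0.71 over 4 genes, and the Notch pathway, with -0.25 over 15. In the first, Nrg4 was at least 2.93-fold lower and Tgfa 2.35-fold lower. In the second, 0 genes passed 2-fold, and Notch3, which is also a pericyte marker, Hes1 and Jag2 had -0.81, -0.77 and -0.77. The Notch median lay at percentile 1.54, and at percentile 3.26 with no floor.

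Chemokines and cytokines were lower as a group, and markers of immune cells went in different directions. Of 28 chemokine and cytokine genes, 6 passed 2-fold lower and 1 higher. Among the 6 were Lif and Cxcl15, which are also expressed by the uterine glands. The neutrophil-attracting chemokine genes Cxcl15 and Cxcl2 were 4.24-fold and 3.33-fold lower, the alarmin gene Il33 at least 3.43-fold lower and Cxcl9 at least 2.40-fold lower, while Csf3 was at least 2.32-fold higher. The median was -0.45, below all random medians. Of 17 macrophage markers 16 had negative ratios, the Fc receptor gene Fcgr3 and the mannose receptor gene Mrc1 were 2.12-fold and 2.03-fold lower, Adgre1 had -0.73 and C1qb -0.72, with a median of -0.36. The joint list of natural killer and T cell markers was higher, with 12 of 14 positive and a median of 0.57 at percentile 99.99. The 1 gene past 2-fold was Cd3d (2.16-fold higher), which was dim at 38.1 and 82.2. Cd3g had -0.12, and Cd3e, Cd4 and Cd8a were under the floor in both arrays. The list therefore does not show that T cell markers rose. The cytotoxic granule genes Gzma and Gzmb had 0.89 and 0.87, and Nkg7 had 0.71. Interferon response genes had a median of 0.26 at percentile 99.6 with 18 of 21 positive and 0 past 2-fold. Bst2 and Gbp3 had 0.79 and 0.66, and Stat2 had a bound of 0.73. Of the 4 measured neutrophil markers, Csf3r, S100a9 and S100a8 had -0.91, -0.54 and -0.35. Ltf was higher, but it is also in the epithelial and estrogen response lists and does not stand for neutrophils alone. The list's median of -0.45 lay at percentile 2.42 and turned to 0.016 with no floor. Among 3 measured B cell genes Ighm was 2.45-fold lower, with another probe set of opposite sign, and Jchain had 0.32.

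Stromal markers were within 2-fold, and endothelial and pericyte markers were lower as groups. None of the 20 stromal fibroblast markers passed 2-fold, and the median was 0.09 at percentile 83.7, or 0.21 at percentile 99.9 with the median over a gene's probe sets. Hand2, a progesterone-induced stromal transcription factor, had 0.63 with another probe set of opposite sign, and Cd34 had 0.53. Of 19 endothelial markers 18 had negative ratios and 0 passed 2-fold. Emcn, Pecam1, Tek and Eng had -0.89, -0.80, -0.76 and -0.76, and the median was -0.53, below all random medians. Pericyte markers had a median of -0.51 over 9 genes at percentile 0.06, with Abcc9 at -0.57 and Mcam at -0.53. Smooth muscle markers had a median of 0.37 over 14 genes at percentile 99.97, with Synpo2, Cnn1 and Actg2 at 0.82, 0.70 and 0.66. Synpo2 had another probe set of opposite sign. Mesothelial markers had a median of 0.29 over 4 genes, within the random range but at percentile 97.7 with no floor, with Wt1 at 0.75. Of 12 blastocyst genes 9 were under the floor in both arrays. Eomes, which is also in the natural killer and T cell list, was above it in both, at 71.6 and 113.

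Epithelial transcripts were abundant in both arrays although epithelial clumps had been discarded during isolation. The keratin genes Krt8 and Krt18 had signals of 2255 and 2822 in control cells and 1703 and 1350 in null cells, and Epcam, the epithelial adhesion molecule, had 987 and 940. Of 24 measured epithelial markers 4 passed 2-fold higher and 3 lower. Those higher were Sprr2f, Ltf, Krt19 (2.05-fold) and Calb1, a calcium-binding protein of the uterine epithelium (5.07-fold, from 750 to 3804). Those lower were Foxa2, Prom1 (2.82-fold) and Krt18 (2.09-fold). The median was -0.15 at percentile 0.60, while the mean was 0.10, so the median and the mean differed in sign.

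Immediate early and heat shock genes, which enzymatic digestion of tissue can induce, were lower in the null array. Of 24 measured genes 22 had negative ratios and 3 passed 2-fold. Egr3, Atf3 and Egr2 were 2.85-fold, 2.56-fold and 2.24-fold lower, with Atf3 going from 2084 to 815, and Fosb had -0.81. The median was -0.46, below all random medians. The higher 3'/5' ratios of Gapdh and Actb went with the same array. Of the 29 lists, 15 had a median outside the central 95% of random medians, against 1.45 for unrelated lists of independent genes.

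**Figure D2:**
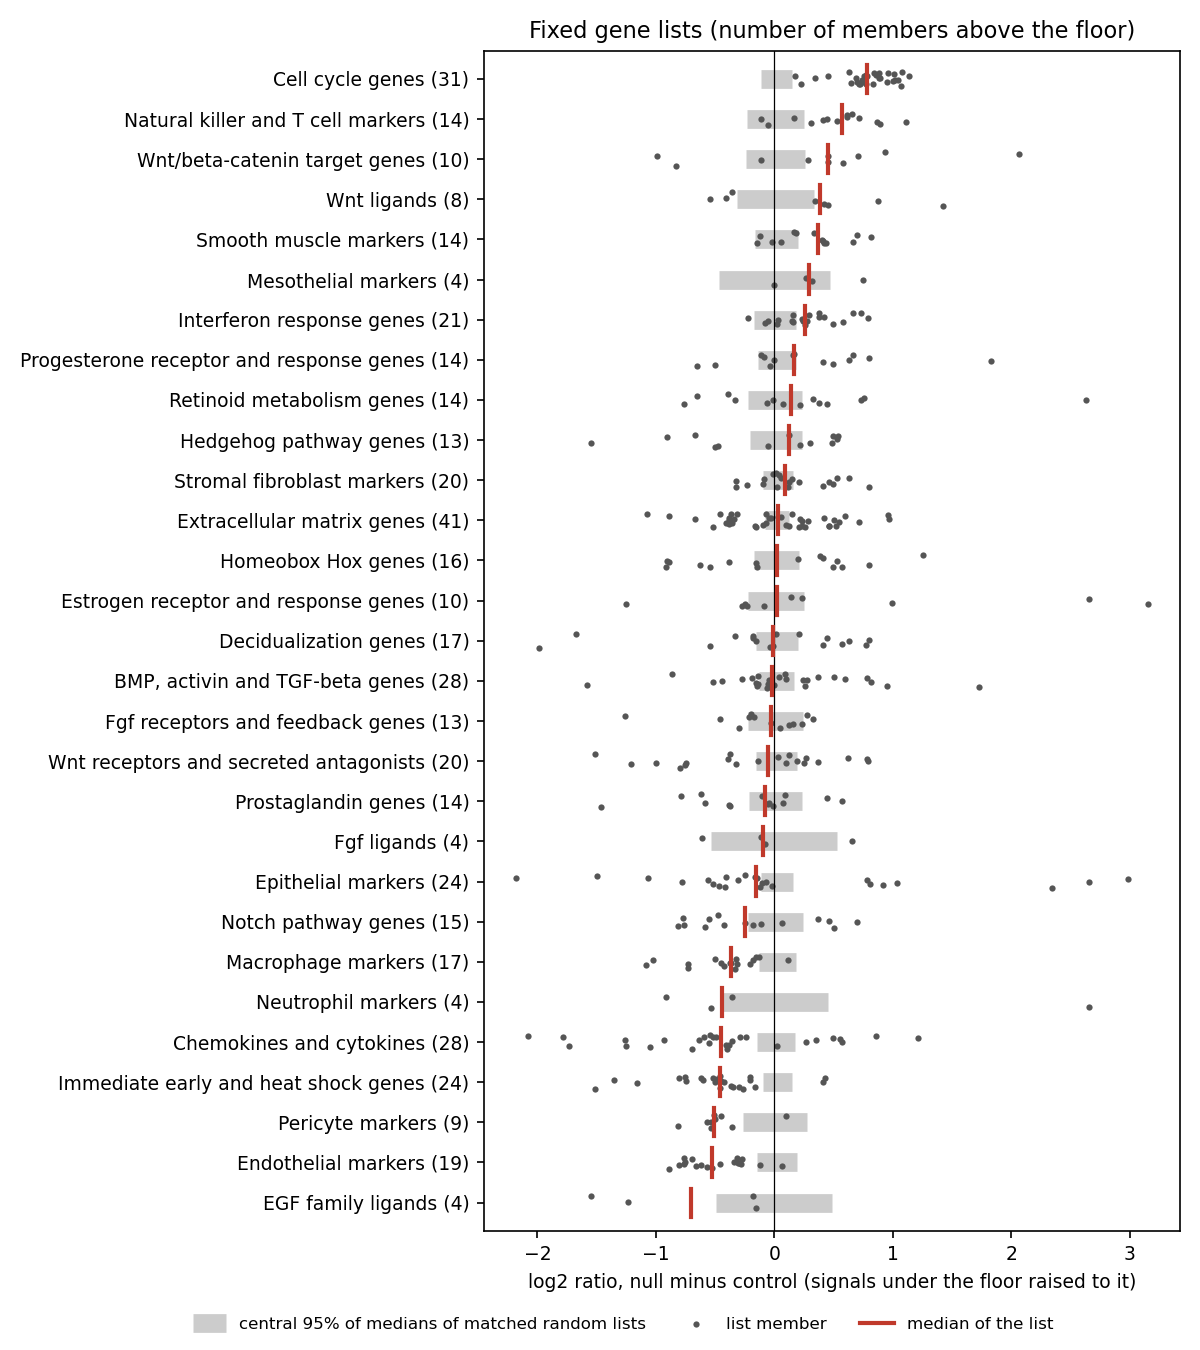
The log2 ratio, null minus control, is on the x axis for the members of each fixed gene list above the floor (grey points, 1 per gene), with the list median as a red bar and the central 95% of medians of matched random lists as a grey band. Cell cycle genes have the highest median at 0.78, and the medians of EGF family ligands, endothelial and pericyte markers lie lowest at -0.71, -0.53 and -0.51.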

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

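The tests of explanations in this part (for gland genes, cell cycle genes and immediate early genes) were chosen after the results were seen. With 1 array per genotype, no sample was compared with others of its group.

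Probe sets with no single gene name lay outside all comparisons, and 55 of the 3212 above the floor were at least 2-fold higher in the null array than in the control array, with 47 at least 2-fold lower. Together that is 3.18%, beside 3.39% of the named genes. The highest measured in both arrays was 1438989_s_at, with signals of 57.7 and 183.

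Several genes known from the uterine glands were among the lowest, while a few other epithelial genes were among the highest. The 8 gland genes (Foxa2, Spink1, Prss28, Prss29, Ttr, Cxcl15, Wfdc3 and Lif) were at least 2.39-fold lower. Among those above the floor in both arrays the largest change was 54.6-fold, and the bounds leave the upper end unknown. The 8 genes were picked after their values were seen, so they do not show that gland genes fell as a group. In contrast, Sprr2f, Ltf, Lcn2 and Calb1 were 5.07-fold to 8.90-fold higher. Of 17 general epithelial genes, picked from the fixed epithelial list after their values were seen, 14 were lower and 3 higher, with a median of -0.16 and an SD of 0.55. The picking left out Foxa2, Prom1, Sprr2f, Calb1 and Ltf, which passed 2-fold, so this small median cannot test the amount of epithelium. Another amount of carried-over epithelium as a whole would move all epithelial genes by about the same factor. In the whole fixed list of 24 measured markers, 4 passed 2-fold higher and 3 lower. Changes in both directions argue against 1 common factor as the whole cause. These values do not exclude slightly less epithelium in the null sample. A smaller share of gland cells within the carried-over epithelium stays open: the SD of the gland ratios was 1.63, beside a probe set SD of 0.27, but 3 of the 8 ratios (Prss28, Prss29 and Ttr) are bounds, so this SD depends on the floor, and genes picked for the pattern cannot test it. A gland gene that other cells also express would also be lowered less, and these arrays cannot separate the sources. The genotype, or a difference in hormone state between the pools, may equally account for it, and neither was tested.

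Cell cycle genes were higher while endothelial, pericyte and macrophage markers were lower. The tables argue against the scaling of the arrays, which would move genes of the same signal alike. The cell cycle median lay 1.31 above the endothelial median, while the central 95% ranges of their signal-matched random lists were at most 0.30 apart from end to end. A higher share of stromal cells at the cost of all other types would lower the markers of every other type. The natural killer and T cell markers had a median of 0.57 and the smooth muscle markers 0.37, so not every other list was lower. Both medians were known when this test was chosen, so it restates them and is no independent test. A change in single cell types, a difference of the pooled mice in the timing of pregnancy, and the genotype stay open as untested.

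Immediate early and heat shock genes were lower, with a median of -0.46. A weaker response to the enzymatic dissociation in the null sample cannot be told apart from the genotype, because each genotype was a single pool and no undissociated sample was measured. Lower RNA integrity in the null sample also stays open: the smaller of the 2 increases in the 3'/5' ratio was 0.38 on the log2 scale, and the distance of each probe set from the 3' end was not used here.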

How the results depend on the processing

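The counts of genes past 2-fold, 188 higher and 213 lower, depended on the floor and the threshold by construction. With no floor they were 1797 and 1772, with a floor at the 65th percentile 97 and 123, at 1.5-fold 804 and 819, and at 3-fold 42 and 59. Under the other 6 alternatives they stayed within 1.5 times the reported counts, and no scaling moved the median gene by more than the 0.0104 of quantile normalization. The Msx1 bounds were -3.49 and -5.40 with the offset and kept within the probe set SD under the 3 scalings. The larger bound, of the brightest probe set, depends on the floor by construction, being -4.29 with the higher floor, and -6.10 as measured with no floor. The Msx2 bound fell under 2-fold with the offset, at -0.92, and with the higher floor Msx2 was under the floor in both arrays. Of 251 list medians under alternatives, 234 were within the SD of random medians. The neutrophil median reversed to 0.016 with no floor, and the cause was not tested. With the median over probe sets, Wnt receptors and antagonists moved to -0.16, beta-catenin targets to 0.32, hedgehog genes to 0.0052, prostaglandin genes to -0.20, Hox genes to 0.13, stromal markers to 0.21 (percentile 99.9) and natural killer and T cell markers to 0.42. With no floor, retinoid genes moved to -0.015, prostaglandin genes to -0.24 (percentile 2.23), Hox genes to 0.20, natural killer and T cell markers to 0.44 and mesothelial markers to 0.55 (percentile 97.7). Hox genes moved to 0.31 (percentile 99.8) with the higher floor and to -0.15 without _x_at and _s_at probe sets or over members above the floor in both arrays, the latter added after the data were seen. Hedgehog genes moved to -0.051 without those probe sets. The progesterone list was at percentile 98.5 with the median over probe sets, and the neutrophil list at 2.67 after centring. Of 493 values of the 62 named genes past 2-fold under alternatives, 61 moved by more than the probe set SD, 30 of them with the higher floor. Of these genes 19 fell under 2-fold in at least 1 alternative, and 3 were under the higher floor in both arrays. No paired analysis was possible because each genotype had 1 array, and for the same reason no replicate could be left out. The single array per genotype, and noise near the floor, limit every value here.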

Other observations

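Single genes outside the fixed lists are given here, chosen after their values were seen, and they stand for no group of genes. The E2F repressor genes E2f8 and E2f7 were 3.88-fold and 2.11-fold higher, and Esco2, Spc25 and Uhrf1 had log2 ratios of 1.37, 1.36 and 1.12. Dio2, which activates thyroid hormone, was 5.26-fold higher, from 726 to 3816. The receptor gene Kit was 3.91-fold lower, and the protease genes Cpa3 and Cma1 had log2 ratios of -1.27 and -1.03. Aqp5, a water channel, was 3.93-fold lower and Lpar3, a lysophosphatidic acid receptor of the uterine epithelium, was 2.37-fold higher.

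The tests of the following 2 hypotheses were chosen before the values of the tested genes were seen, but the minimum of 3 genes for a decision was set afterwards. By the bounds written beforehand alone, the first value would have counted against its hypothesis and the second for it. Under the hypothesis that estrogen-responsive epithelial genes were higher in the null array, other Sprr2 genes should follow Sprr2f. Only Sprr2k was above the floor, and only in the null array, so the sign of its ratio followed from the filter. Its bound of 0.35 may hide a larger ratio because its control signal was under the floor, so the test decided nothing. Under the hypothesis that granzyme genes of uterine natural killer cells were higher, other granzyme genes should follow Gzmf. Gzmd and Gzme were above the floor in the null array only, with a median bound of 0.61, so the sign of their ratios followed from the filter. Gzmg, Gzmk, Gzmm and Gzmn were under the floor in both arrays. Moreover, 2 genes whose probe sets may also bind each other's transcripts or those of Gzmf are too few to decide.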
